A study of Mus musculus with 12 samples.

How the data were processed

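RNA was measured in placenta and diaphragm of WT and MatKO mice, 3 libraries per group and 12 in all. Per the labels' protocols, a column kit (RNeasy plus mini) yielded the RNA, and 40 ng of total RNA entered a SMART-seq Total RNA preparation that removes ribosomal sequence with ZapR. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10b to the mouse genome build mm39 and counted with featureCounts 2.0.3. The table deposited by the authors holds estimated counts per gene, not normalized, in which some reads were shared between genes: 24.0% of the values above 0 are not whole. Its alignment files carry repeat_rm in their names, a term that the sources used here do not define. Neither the annotation release nor the strand setting is stated in these sources. The table itself tells strands apart at least in part: Mir136 lies inside Mir3071 on the opposite strand, and MatKO diaphragm 1 had 16 counts for Mir136 and 128 for Mir3071, where a count blind to strand would share such reads alike. A total RNA library reads the stretch of the host transcript that holds a microRNA precursor, not the mature microRNA.

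Samples were grouped by the tissue and genotype in their labels. The title of WT placenta replicate 3 says KO, while its genotype label and library name say WT, and it was used as WT. All libraries carry the same batch label, 1. The labels do not say that replicates are separate animals, so the tests measure the spread between these samples. Another 2 columns of the table match no sample and were not used. Gene symbols came from GENCODE M21, an annotation of the older build GRCm38 that served for names only: 51449 of 78238 gene IDs (65.8%) had a symbol, and these hold 99.2% of the counts. No gene of the mitochondrial genome is in the table, so mitochondrially encoded genes were not measured.

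Estimated counts were rounded and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM size factors and the filterByExpr function at its minimum count of 10 and minimum total of 15. Each tissue was fitted alone, MatKO against WT, without covariates. The difference of the genotype effect between tissues was tested in 1 fit of the 4 groups. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Errors of log2 fold changes of genes are standard errors derived from the F statistic, as the absolute log2 fold change over its square root. For genes with few counts they depend on the prior count, as the fold changes do. Errors of CPM (counts per M counts) are SDs over 3 libraries. Library totals ran from 6.97 to 10.9 M counts, so that 3 counts, the upper limit that a count of 0 allows at 95% confidence, stand for 0.276 to 0.430 CPM. Such limits cover counting error only.

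Before the data were examined, 48 lists of genes were fixed from general knowledge of both tissues, 21 for both, 11 for placenta and 16 for diaphragm. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and adjusted over the lists of that tissue. Camera with an estimated correlation and fry were run beside it. The named genes were fixed by a rule at the same time. It took Rtl1 and its neighbours, and the 10 largest changes in each direction among called autosomal genes with a named symbol, a mean log2 CPM of at least 1 and groups that do not overlap. It also took up to 4 called members per list and, where a list passed with fewer than 2 of these, its 2 members with the smallest p, as well as genes that mark sex. For the difference between tissues it took the 5 genes with the smallest adjusted p in each direction.

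The settings were tested on simulated data of the same size, with 200 genes changed. In placenta 40.0%, 60.9% and 91.5% of genes changed 1.5, 2 and 4 times were called, and 2.46% of calls were false. In diaphragm these shares were 24.2%, 75.8%, 95.5% and 5.84%. For the difference between tissues they were 9.09%, 31.2%, 53.0% and 10.3%. With no change simulated, 3 genes were called in placenta and 1 in diaphragm. A list moved 1.5 times ranked 1 in both tissues, with 0 other lists called. Genes were drawn independently and no library was given background reads, so lists whose members move together were not tested. With the real libraries, other groupings called up to 10 lists in placenta and 12 in diaphragm.

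Alternatives fixed at that time were DESeq2 1.42.0 size factors and Wald test, limma-voom, no filter, a filter at a CPM of 1 in 3 libraries, sex as a covariate, males only (1 MatKO against 3 WT), the replicate number as a block, a joint fit of 12 libraries, genes off X and Y, and each replicate left out (for the correlation across tissues, replicate 3 only). Males only for the lists, the difference between tissues and the correlation, the correlation without replicates 1 and 2, and subtraction of background reads, were added after seeing the data. For each library it takes off the reads per kb over autosomal olfactory receptor genes times a gene's exon length, or 2 times that. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.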

Results

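Total RNA of mouse placenta and diaphragm was sequenced in 12 libraries, 3 each of WT and MatKO in both tissues. MatKO is the label for the maternal knockout of Rtl1, a retrotransposon-derived gene of the imprinted Dlk1-Dio3 domain that is expressed from the paternal chromosome and is known to act in placental vessels and in skeletal muscle. The series asks how transcripts of these mice differ from WT, here in each tissue and then between tissues. Totals were 8.08 to 9.90 M counts in WT placenta, 7.48 to 8.87 M in MatKO placenta, 8.03 to 10.9 M in WT diaphragm and 6.97 to 8.32 M in MatKO diaphragm. All WT libraries are labelled male. In both tissues MatKO replicates 1 and 3 are labelled female and replicate 2 male, and replicate 3 is also labelled abnormal.

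Trophoblast and muscle transcripts followed the tissue labels. Tpbpa, a marker of the junctional zone of the placenta, lay between 7867 and 10825 CPM in the 6 placentas and at most at 0.237 CPM in the diaphragms, while Myh8, the perinatal myosin, lay at 73531 CPM or more in the diaphragms and at most at 3.81 CPM in the placentas. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y followed the sex labels, with at most 1 count in any female library. Xist, the RNA of the inactive X, lay at 884 and 1001 CPM in the female placentas, at 85.4 to 144 CPM in the male placentas and at most at 0.119 CPM in the male diaphragms.

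MatKO placentas 1 and 3, the female ones, stood apart in how many genes had reads, with 50103 and 49231 against 32809 to 38171 in the other 4 placentas. Olfactory receptor genes, which are largely silent outside the nose, held 1.09 and 0.876 reads per kb per 10 M counts there, against 0.0904 to 0.259 in the other placentas and 0.0618 to 0.205 in the diaphragms. Vomeronasal receptor genes held 0.775 and 0.691 there, against 0.0781 to 0.176 in the other placentas.

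**Figure D1:**
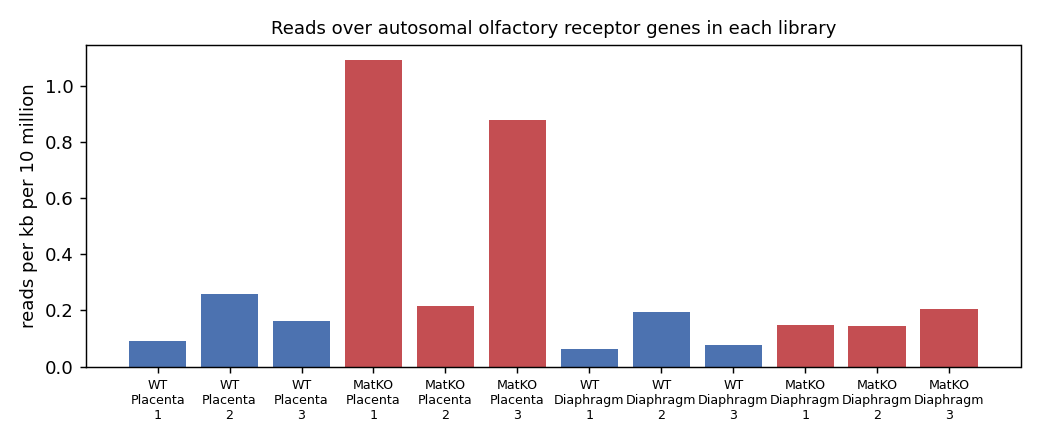
Reads over 1101 autosomal olfactory receptor genes in each library, per kb of exon and per 10 M counts (y axis), with 1 bar per library (blue WT, red MatKO). MatKO placentas 1 and 3 reach 1.09 and 0.876, and every other library stays at or under 0.259.

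Rtl1 was higher in MatKO in both tissues. In placenta it rose 4.21-fold, from 106 ± 4.22 to 448 ± 24.4 CPM (SD, n = 3; log2 fold change 2.07 ± 0.08, edgeR adjusted p = 2.1e-09). In diaphragm it rose 3.74-fold, from 397 ± 20.6 to 1486 ± 141 CPM (1.90 ± 0.08, adjusted p = 6.2e-10). Each MatKO library lay above each WT library of its tissue. WT placenta 3, whose title says KO, had 861 counts of Rtl1. The other WT placentas had 1010.9 and 874 and the MatKO placentas 3430 or more, so its level goes with its genotype label. The gene (ENSMUSG00000085925.4) spans 109555627 to 109566764 on the minus strand of chromosome 12 (mm39).

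An antisense transcript through Rtl1 carries microRNAs known to cleave Rtl1 RNA, and 4 of the 7 precursors measured in diaphragm were lower in MatKO. Mir434 fell by 5.90 ± 0.47 on the log2 scale (adjusted p = 1.9e-06), from 8.50 ± 0.89 to 0.131 ± 0.139 CPM. Its counts in the MatKO libraries were 2, 0 and 1, so the fitted size depends on the prior count. Mir431 fell by 3.45 ± 0.63 (adjusted p = 0.0058), Mir432 by 2.13 ± 0.33 (0.0019) and Mir433 by 1.13 ± 0.27 (0.030). Values of Mir136 (-0.67 ± 0.31, adjusted p = 0.37) and Mir127 (-0.53 ± 0.31, 0.54) did not pass. Mir3071, the list's 1 member on the strand of Rtl1, rose by 2.06 ± 0.19 (1.0e-05). The same 1 was higher and 4 were lower when adjusted over the list alone. The list as a whole was lower (Rtl1 antisense microRNA precursors, camera adjusted p = 0.0011, and adjusted p = 0.45 with an estimated correlation). Mir431 in diaphragm missed the threshold without WT replicate 3 (adjusted p = 0.056), and Mir433 in diaphragm missed it without WT replicate 2 (0.15), WT replicate 3 (0.13), MatKO replicate 1 (0.13) or MatKO replicate 3 (0.074). With sex as a covariate 3 of the 4 lower calls ended, Mir431 (0.37), Mir433 (0.63) and Mir432 in diaphragm (0.11), and in males only Mir431 (0.067) and Mir433 (0.54) did.

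**Figure D2:**
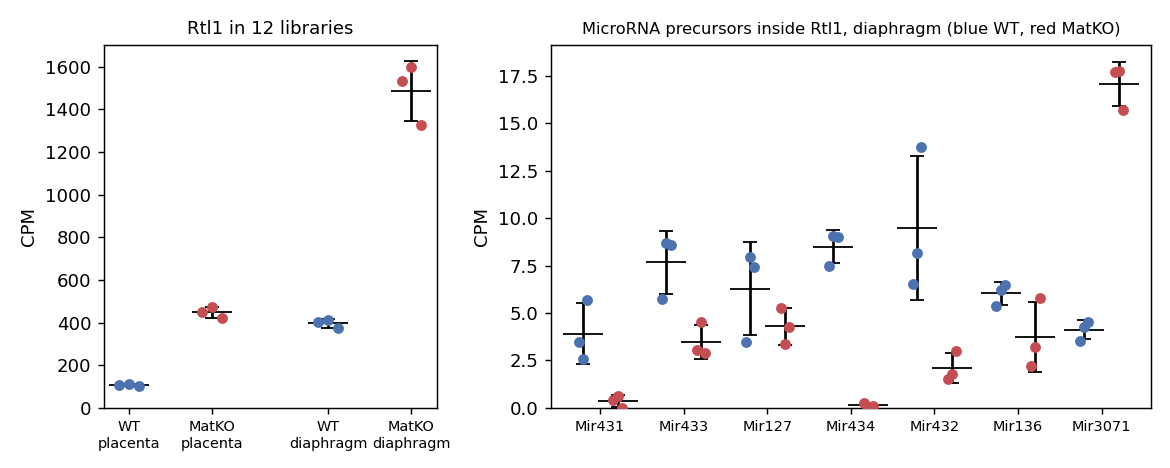
CPM of Rtl1 in each of the 12 libraries (left) and of the microRNA precursors inside it in each diaphragm library (right), with points for libraries, lines for means and bars for SD (n = 3; blue WT, red MatKO). Rtl1 and Mir3071, which lie on the same strand, are higher in MatKO, while Mir434 goes from 8.50 to 0.131 CPM.

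Of the other genes of the domain, Dlk1 was called in placenta. Mir3071, which lies inside Rtl1 on its strand and may count the same RNA, was called there too. In placenta Dlk1, a paternally expressed gene for a growth-regulating membrane protein, rose from 204 ± 11.8 to 302 ± 24.9 CPM (0.57 ± 0.09, adjusted p = 0.0039). Dlk1 in placenta missed the threshold without WT replicate 2 (adjusted p = 0.065) or WT replicate 3 (0.10). The maternally expressed noncoding RNAs did not pass there: Meg3 was at 0.67 ± 0.18 (adjusted p = 0.13), Rian at 0.58 ± 0.19 (0.25) and Mirg at -0.01 ± 0.20 (0.99). Adjusted over the list alone, 2 of the 3 were higher, while camera gave adjusted p = 0.13. Their mean was 0.56 and 0.66 in MatKO placentas 1 and 3, which hold more reads over silent genes, and -0.03 in MatKO placenta 2, against -0.13 to 0.19 in WT. Mir3071 rose in placenta (2.61 ± 0.49, adjusted p = 0.015), where only 3 precursors had enough counts for a test and the others, Mir433 (0.32 ± 0.54) and Mir127 (0.23 ± 0.55), were not called. As a list these 3 did not pass (adjusted p = 0.068). The untested Mir432 had 10, 8 and 8 counts in WT placentas and 2, 3 and 2 in MatKO, Mir431 had 2, 7 and 1 and then 0 (at most 3), 1 and 1, Mir434 had 12, 6 and 2.5 and then 3, 1 and 5, and Mir136 had 1, 7 and 3 and then 4, 9 and 4. Mir3071 in placenta missed the threshold without WT replicate 1 (adjusted p = 0.055), WT replicate 2 (0.065), WT replicate 3 (0.096) or MatKO replicate 3 (0.13). In diaphragm Dlk1 (0.12 ± 0.07, adjusted p = 0.56), Meg3 (-0.04 ± 0.32), Rian (-0.08 ± 0.07) and Mirg (-0.08 ± 0.27) were not called. The difference between tissues did not pass for Dlk1 (adjusted p = 0.23) or Rtl1 (0.77). Dio3 had too few counts for a test in either tissue.

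In MatKO placenta, the list of endothelial markers was higher, with 6 of 18 genes called, and the list of hypoxia response genes was lower, with 1 of 20 called. With an estimated correlation both had adjusted p = 0.31. Among the endothelial cell markers, Eng, a co-receptor for TGF-beta family ligands, rose by 0.72 ± 0.09 on the log2 scale (adjusted p = 8.8e-04, n = 3 per group). The tight junction gene Cldn5 rose by 0.98 ± 0.15, from 12.1 ± 0.261 to 23.8 ± 3.32 CPM, the sialomucin Emcn by 1.39 ± 0.25 and the receptor Tie1 by 0.63 ± 0.12. Cldn5 lost its call without WT replicate 3, and Emcn without WT replicate 1 or 3 or MatKO replicate 1 or 3. Tie1 lost it without WT replicate 1, 2 or 3 or MatKO replicate 3. Of the 18 measured, 0 were called lower, and 11 were higher when adjusted over the list alone, with a median of 0.37. The list passed camera (adjusted p = 2.1e-05) and fry (0.018). Its mean was 0.34, 0.45 and 0.39 in MatKO placentas 1, 2 and 3, and -0.03 to 0.03 in WT. With no filter on low counts the camera call of endothelial cell markers was lost (adjusted p = 0.24).

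Among angiogenic signalling genes, the apelin receptor Aplnr rose by 2.57 ± 0.35 (adjusted p = 0.0016), its ligand Apln by 1.67 ± 0.24, Notch1 by 0.58 ± 0.09 and the semaphorin and VEGF co-receptor Nrp2 by 0.60 ± 0.10. Of 24 measured, 6 were higher and 0 lower. Adjusted over the list alone, 9 were higher and 2 lower, with a median of 0.17 and camera adjusted p = 0.041. The list's adjusted p was 0.50 with an estimated correlation. The call of angiogenic signalling genes was lost without WT replicate 1 (0.13), WT replicate 2 (0.33), WT replicate 3 (0.16), MatKO replicate 2 (0.30) or MatKO replicate 3 (0.14), and its median fell to 0.06 without WT replicate 2. Mural cell markers, genes of pericytes and vascular smooth muscle, were higher as a list (median 0.18, adjusted p = 0.026, and adjusted p = 0.50 with an estimated correlation). Mcam, 1 of 11 measured, rose by 0.64 ± 0.09, and Abcc9 stood at 0.72 ± 0.21 without passing (adjusted p = 0.14), while 3 were higher when adjusted over the list alone. Without WT replicate 2 (0.20), WT replicate 3 (0.20), MatKO replicate 2 (0.29) or MatKO replicate 3 (0.070) mural cell markers were not called. With sex as a covariate neither list was called (0.29 for angiogenic and 0.13 for mural), and with no filter on low counts camera's direction for both turned to lower, without a call.

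The hypoxia response genes were lower as a list, with a median of -0.15 (camera adjusted p = 1.5e-04, and adjusted p = 0.31 with an estimated correlation; fry 0.018). Egln3, a prolyl hydroxylase induced by low oxygen, fell from 90.9 ± 6.33 to 59.0 ± 2.71 CPM (-0.62 ± 0.09, adjusted p = 0.0028). Adjusted over the list alone, 5 were lower. Bnip3, a mitochondrial mitophagy gene, stood at -0.33 ± 0.08 (adjusted p = 0.083). The list's mean was -0.21, -0.15 and -0.20 in MatKO placentas 1, 2 and 3, and -0.04 to 0.03 in WT.

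**Figure D3:**
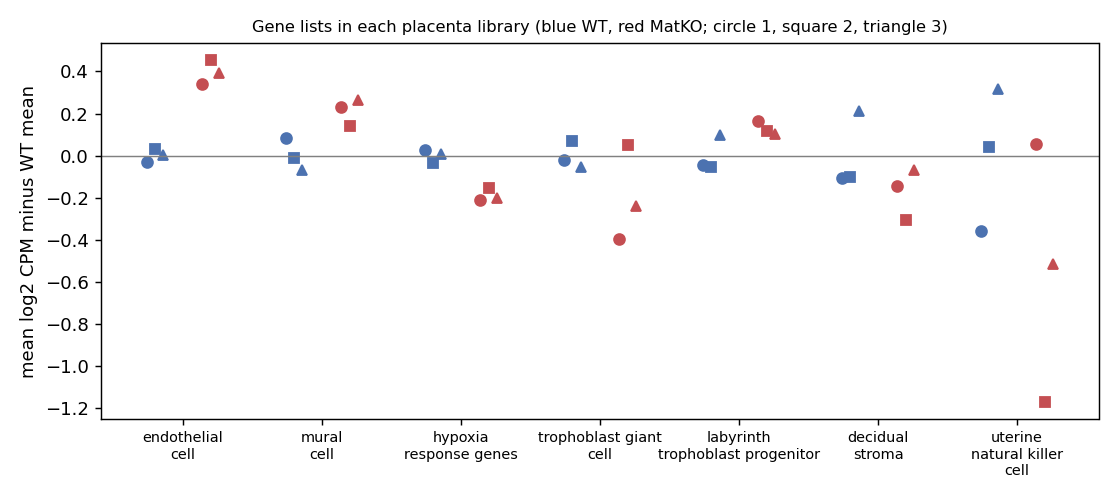
Mean log2 CPM of the members of 7 gene lists in each placenta library, less the mean of the 3 WT libraries (y axis), with circles, squares and triangles for replicates 1, 2 and 3 (blue WT, red MatKO). Endothelial markers lie at 0.34 to 0.45 in every MatKO placenta, while giant cell markers differ between MatKO placenta 2 (0.05) and MatKO placentas 1 and 3 (-0.40 and -0.24).

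Trophoblast and maternal lists in placenta shifted less evenly. Trophoblast giant cell markers were lower (18 measured, 0 called and 0 when adjusted over the list alone, median -0.24, adjusted p = 0.0066, and adjusted p = 0.50 with an estimated correlation), with the lactogen Prl3b1 at -0.34 ± 0.10 (adjusted p = 0.16) and the proliferin Prl2c3 at -0.35 ± 0.11 (0.20). Their mean was -0.40 and -0.24 in MatKO placentas 1 and 3, the libraries with more reads over silent genes, and 0.05 in MatKO placenta 2, against -0.05 to 0.07 in WT. Without MatKO replicate 1 trophoblast giant cell markers were not called (adjusted p = 0.15), and spongiotrophoblast markers were not either (0.15). With sex as a covariate camera's direction for trophoblast giant cell markers turned (median -0.0260, adjusted p = 0.84), as it did in males only (-0.0244, 0.93), and spongiotrophoblast markers were not called (0.57 and 0.54), nor were these with background reads taken off at 2 times the rate (0.058). Spongiotrophoblast markers were lower as a list (median -0.20, adjusted p = 0.022, and adjusted p = 0.50 with an estimated correlation), although Cdkn1c, the 1 called of 16, rose by 0.47 ± 0.08. This maternally expressed cell cycle inhibitor was the 1 higher when adjusted over the list alone, against 3 lower. Tpbpb was at -0.39 ± 0.11 (adjusted p = 0.13). The mean of these markers was -0.30, -0.06 and -0.10 in MatKO placentas 1, 2 and 3 and -0.10 to 0.12 in WT, so the groups overlap.

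Decidual stroma markers were lower (13 measured, median -0.17, adjusted p = 0.024, and adjusted p = 0.50 with an estimated correlation), with Hoxa10 at -0.31 ± 0.11 (adjusted p = 0.25). Their mean was -0.14, -0.31 and -0.07 in MatKO placentas 1, 2 and 3 and -0.11, -0.10 and 0.21 in WT, so the groups overlap and only WT placenta 3 is high. Bmp2, a signal that also acts in vessels, was their 1 called member and rose by 1.41 ± 0.17, and it was also the 1 higher when adjusted over the list alone. Uterine natural killer cell markers had a median of -0.62 over 7 measured (adjusted p = 0.028, and adjusted p = 0.50 with an estimated correlation), 0 of them called and 0 when adjusted over the list alone. Gzmc was at -0.97 ± 0.33 and Gzmd at -0.62 ± 0.28, both granzymes. The mean of these cells' markers was 0.06, -1.17 and -0.52 in MatKO placentas 1, 2 and 3 against -0.36 to 0.32 in WT, and Xist was lowest in the same MatKO placenta 2. Decidual stroma markers were not called without WT replicate 3 (0.15) or MatKO replicate 2 (0.052), nor with background reads taken off at 2 times the rate (0.065), and uterine natural killer cell markers were not without WT replicate 1 (0.067), WT replicate 2 (0.15), WT replicate 3 (0.21), MatKO replicate 2 (0.40) or MatKO replicate 3 (0.050).

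Replication-dependent histone genes were lower (20 measured, 0 called, 0 when adjusted over the list alone, median -0.13, adjusted p = 0.041), with Hist1h4d at -0.40 ± 0.14 and Hist1h4c at -0.39 ± 0.15. Glucocorticoid response genes were lower too (12 measured, 0 called, 0 when adjusted over the list alone, median -0.15, adjusted p = 0.041), with the clock gene Per1 at -0.29 ± 0.09 and the factor Klf9 at -0.28 ± 0.10. Both had adjusted p = 0.50 with an estimated correlation. Replication-dependent histone genes were not called without MatKO replicate 1 (0.099) or MatKO replicate 3 (0.16), and glucocorticoid response genes were not without WT replicate 3 (0.15) or MatKO replicate 3 (0.089). Glucocorticoid response genes had means of -0.04, -0.06 and -0.13 in MatKO placentas 1, 2 and 3 and -0.15, 0.02 and 0.13 in WT, so these groups overlap. The histone mean was -0.21 and -0.28 in MatKO placentas 1 and 3 and -0.01 in MatKO placenta 2, against -0.05 to 0.04 in WT. Taking off background reads ended both calls (adjusted p = 0.080 and 0.068), and so did sex as a covariate, where the histone median turned to 0.0279 (0.86 and 0.28).

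Imprinted genes outside the domain were mostly not called. Paternally expressed Mest rose by 0.59 ± 0.10, Zdbf2 by 0.50 ± 0.09 and Peg13 by 0.50 ± 0.11, with 3 of 27 higher and 5 when adjusted over the list alone (camera adjusted p = 0.068). Of the 30 maternally expressed genes of the fixed list, 1 was higher, and 2 were higher and 1 lower when adjusted over the list alone. Their median (0.01) and mean (0.08) were above 0 while camera pointed lower (adjusted p = 0.92). The list thus holds at most 1 of Cdkn1c (0.47) and Kcnk9 (2.74), both maternally expressed and called higher in placenta. Glycogen trophoblast markers were not called as a list (adjusted p = 0.067), although Prl7b1 rose by 0.60 ± 0.12 and Igfbp7 by 0.44 ± 0.10. In that list 2 of 10 were higher, and 3 when adjusted over the list alone. Labyrinth trophoblast progenitor markers (0.44), syncytiotrophoblast layer I markers (0.76) and syncytiotrophoblast layer II markers (0.067) were not called, with 0, 0 and 0 called genes. Over the list alone 1 gene was lower in each syncytiotrophoblast list and none was in the progenitor list. Median (0.03) and mean (-0.02) differed in sign for layer I. The remaining lists outside the domain had adjusted p of 0.068 or more and 0 called genes. Among them, macrophage and leukocyte markers had a median of -0.05 and a mean of 0.02, and immediate early genes a median of 0.00 and a mean of 0.09, while camera pointed lower for both (0.90 and 0.92).

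In all, 183 of 16437 genes were called in placenta, 160 higher and 23 lower, and 90 of them changed at least 2-fold (88 higher, 2 lower). Groups did not overlap for any of the 183, against 15.9% of all genes tested and 10% by chance for 3 against 3. The largest lower changes were in Prx, a scaffold protein gene (-1.27 ± 0.24), Gkn2 (-1.15 ± 0.24), the matrix gene Ltbp2 (-0.99 ± 0.16), Fam174b (-0.88 ± 0.18), Fam20c, a secretory kinase (-0.69 ± 0.12), Ly6g6c (-0.69 ± 0.16), Sord, sorbitol dehydrogenase (-0.62 ± 0.14), Slc39a4, a zinc transporter (-0.55 ± 0.10), and Efna1 (-0.54 ± 0.10). Kcnk9, a maternally expressed imprinted potassium channel gene, rose by 2.74 ± 0.26, from 1.66 ± 0.21 to 11.2 ± 1.74 CPM (adjusted p = 8.0e-05). The other largest increases were in genes with mean WT levels under 1 CPM: AC142100.3 (3.77 ± 0.72), AC161438.1 (3.74 ± 0.61), Fam81a (3.31 ± 0.58), Acsl6 (3.20 ± 0.62), Camk2a (3.01 ± 0.54), Sox2ot (2.88 ± 0.63), Adgrb3 (2.85 ± 0.61), Nek10 (2.80 ± 0.56) and Dnah3 (2.72 ± 0.55). Taking off background reads ended the call of Nek10 in placenta (3.05, adjusted p = 0.055), Sox2ot in placenta (3.49, 0.089), Sord in placenta (-0.60, 0.056) and Ly6g6c in placenta (-0.67, 0.055). At 2 times the rate it also ended that of Acsl6 in placenta (3.72, 0.067), Dnah3 in placenta (3.21, 0.075) and Prx in placenta (-1.32, 0.053).

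Leaving out MatKO placenta 2 raised the count to 2012, or to 780 with background reads taken off, while it was 60, 114 and 53 without WT replicate 1, 2 or 3, and 84 and 76 without MatKO replicate 1 or 3. The fit without MatKO placenta 2 sets MatKO placentas 1 and 3, both female and with more reads over silent genes, against male WT. Genotype cannot be told apart from sex or from these reads in it. With sex as a covariate 55 genes were called, 46 of them among the 183, and in males alone, where 1 MatKO is set against 3 WT and WT alone gives the spread, 87, with 63 shared. All 183 kept their direction with sex, and the median ratio of their log2 fold changes to those without it was 0.888 (0.889 in males alone). The sex term leaves the genotype effect to rest on the 1 male MatKO placenta. Since groups did not overlap for any of the 183, that library already lay on the called side of every WT. The kept direction was thus fixed in advance and says nothing about sex. Of the 38 called genes that the naming rule picked beside Rtl1, 7 passed whichever library was left out and 10 with sex as a covariate. The 6 that passed in all of these and with background reads taken off are Kcnk9, Bmp2, Eng, Mcam, Aplnr and Egln3. The other of the 7, Apln in placenta, was lost with sex as a covariate (1.36, adjusted p = 0.10). The number that passed was 13, 23 and 9 without WT replicate 1, 2 or 3, and 20, 38 and 16 without MatKO replicate 1, 2 or 3.

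In MatKO diaphragm, genes of fast muscle fibres fell nearly as a whole. Pvalb, the calcium buffer parvalbumin, fell from 55.3 ± 8.37 to 4.91 ± 1.34 CPM (-3.48 ± 0.18 on the log2 scale, adjusted p = 2.6e-08, n = 3 per group). Actn3, the fast fibre Z-disc actinin, fell by 0.95 ± 0.07, Myh4, the fastest myosin heavy chain, by 0.81 ± 0.08 and the myosin kinase Mylk2 by 0.73 ± 0.08. Of 17 fast fibre genes measured, 16 fell and 0 rose, and 16 were lower when adjusted over the list alone, with a median of -0.48. The 1 that did not pass was Myh1 (-0.41 ± 0.16, adjusted p = 0.40). The list passed camera (adjusted p = 3.9e-17, and adjusted p = 0.45 with an estimated correlation) and fry (0.023). Its mean was -0.66, -0.68 and -0.68 in MatKO diaphragms 1, 2 and 3, and -0.11 to 0.09 in WT.

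Other contractile genes were divided. Excitation-contraction coupling genes fell in 6 of 17 and rose in 0, and 10 were lower when adjusted over the list alone (median -0.24, adjusted p = 4.0e-04, and adjusted p = 0.45 with an estimated correlation). They include Hrc, a calcium-binding protein of the reticulum (-0.52 ± 0.07), Sypl2 (-0.47 ± 0.07), the triad gene Trdn (-0.51 ± 0.08) and Jsrp1 (-0.40 ± 0.09). In the 1 male MatKO diaphragm the adjusted p of the excitation-contraction coupling genes was 0.058. Slow fibre genes were not called as a list (adjusted p = 0.75, median -0.07 and mean 0.07, camera pointing lower): the slow myosin Myh7 (-0.27 ± 0.06) and Myoz2 (-0.28 ± 0.07) fell and Csrp3, a stretch-responsive Z-disc protein gene, rose by 1.63 ± 0.19. Adjusted over the list alone 3 of the 12 were higher and 4 lower. Other sarcomere and Z-disc genes fell in 4 of 25 and rose in 0, among them the thin filament ruler Neb (-0.32 ± 0.05), skeletal actin Acta1 (-0.32 ± 0.07), Myom1 (-0.28 ± 0.06) and Tcap (-0.37 ± 0.09). Adjusted over the list alone 5 were higher and 7 lower, median (-0.07) and mean (0.11) differed in sign, and camera pointed lower with adjusted p = 0.72. Of 7 developmental myosin genes, Myh8 (-0.28 ± 0.05) and the fetal actin Actc1 (-0.28 ± 0.07) fell and embryonic Myh3 stood at 0.18 ± 0.10 without passing (adjusted p = 0.52). Adjusted over the list alone 3 were higher and 2 lower (camera adjusted p = 0.74).

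**Figure D4:**
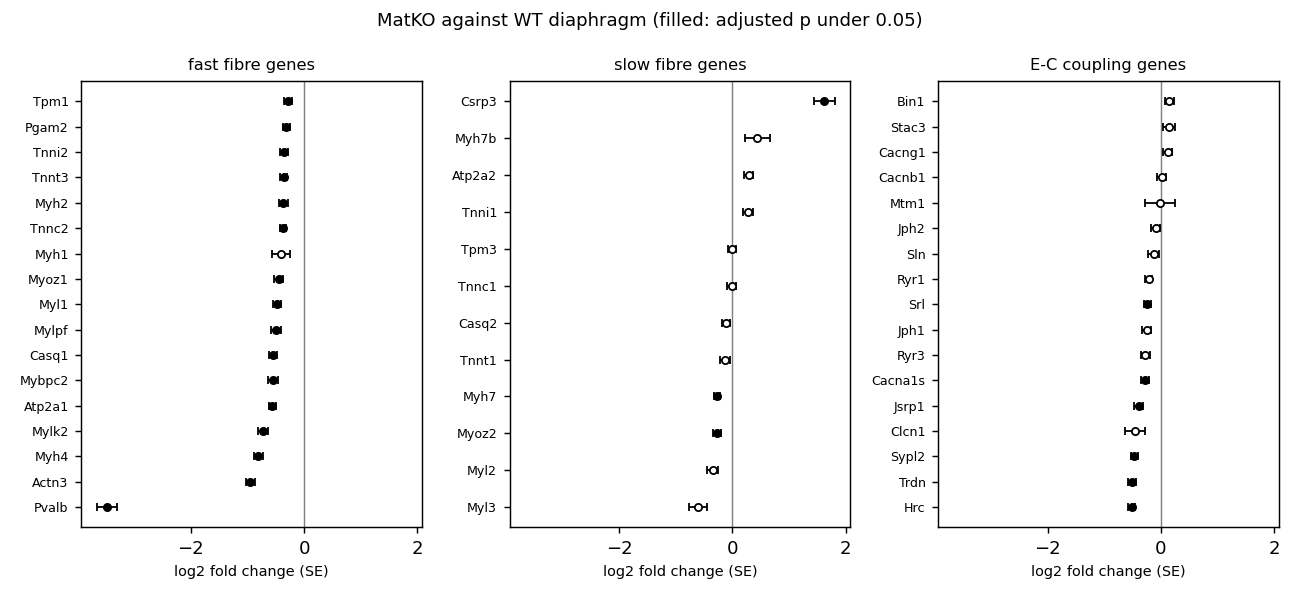
Log2 fold change of MatKO against WT diaphragm (x axis; bars, SE; n = 3 per group) for each measured fast fibre, slow fibre and excitation-contraction (E-C) coupling gene, filled where the adjusted p is under 0.05. All 17 fast fibre genes lie under 0 and 16 are filled, while slow fibre genes lie on both sides.

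The list of genes known to respond to loss of nerve input or to wasting was higher, with 4 of 17 called (adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation). The ubiquitin ligase Fbxo32 (atrogin) rose by 1.40 ± 0.11 from 31.4 ± 4.68 to 83.5 ± 6.38 CPM (adjusted p = 1.9e-06), the deacetylase Hdac4 by 0.93 ± 0.09, Runx1 by 0.96 ± 0.14 and the receptor Eda2r by 0.68 ± 0.16. Of the muscle atrophy and denervation genes 0 were called lower, against 5 higher and 1 lower when adjusted over the list alone (median 0.13). Without MatKO replicate 3, labelled abnormal, the muscle atrophy and denervation genes were not called (0.20), nor were they in males alone (0.25) or with sex as a covariate (0.23). Neuromuscular junction genes rose in 4 of 16 and fell in 0, also when adjusted over the list alone: the fetal acetylcholine receptor subunit Chrng (1.04 ± 0.12), its partner Chrnd (0.81 ± 0.16), the receptor kinase Musk (0.62 ± 0.11) and the sodium channel Scn4a (0.49 ± 0.08). That list did not pass camera (adjusted p = 0.35), with a median of 0.00 and a mean of 0.11. Among 20 myogenic regulators and fusion genes, Mstn, myostatin, fell by 1.56 ± 0.19 and was the 1 call, against 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.57).

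Immediate early genes were higher in diaphragm as a list (3 of 18 called, all up, and 6 when adjusted over the list alone, median 0.50, adjusted p = 3.9e-06, and adjusted p = 0.45 with an estimated correlation), with Fos at 1.19 ± 0.20, Atf3 at 1.58 ± 0.27 and the phosphatase Dusp1 at 0.60 ± 0.13. Fos, Atf3 and Dusp1 each lost the call whichever WT replicate was left out. Atf3 also lost it without MatKO replicate 2, and Dusp1 without MatKO replicate 1 or 2. ATF4 and unfolded protein response genes were higher as a list (1 of 17 called, Atf3, and 5 when adjusted over the list alone, median 0.22, adjusted p = 7.5e-04, and adjusted p = 0.45 with an estimated correlation), with the mitochondrial folate enzyme Mthfd2 at 1.02 ± 0.28 (adjusted p = 0.062). Of 16 p53 target genes, Eda2r rose and Ccng1 fell by 0.70 ± 0.08, against 5 higher and 1 lower when adjusted over the list alone (median 0.31, adjusted p = 0.043, and adjusted p = 0.45 with an estimated correlation). The p53 target genes were not called without WT replicate 1 (0.11), WT replicate 2 (0.075), MatKO replicate 1 (0.075) or MatKO replicate 2 (0.16), nor with background reads taken off at 2 times the rate (0.054).

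Nuclear oxidative phosphorylation genes were lower as a list, with 3 of 27 called, the subunits Cox7b (-0.38 ± 0.08) and Atp5a1 (-0.29 ± 0.07) and the electron carrier Cycs (-0.29 ± 0.07), and 13 lower when adjusted over the list alone (median -0.19, adjusted p = 2.5e-07, and adjusted p = 0.51 with an estimated correlation). None of the 27 was higher by any amount. Interferon response genes were lower as a list, with a median of -0.80 over 18 genes (adjusted p = 5.5e-07, and adjusted p = 0.45 with an estimated correlation), 1 called and 1 when adjusted over the list alone, the guanylate-binding Gbp3 (-0.86 ± 0.21). Irf7 stood at -1.06 ± 0.35 (adjusted p = 0.15). The interferon list's mean was -0.88, -1.09 and -0.25 in MatKO diaphragms 1, 2 and 3, and -0.14, -0.22 and 0.35 in WT, so MatKO diaphragm 3 lies beside WT diaphragm 2. Glucocorticoid response genes were not called as a list (0.12): Pdk4, a kinase that restrains pyruvate oxidation, rose by 1.46 ± 0.11, while Klf9 (-0.52 ± 0.09) and Fkbp5 (-0.50 ± 0.10) fell, with 1 higher and 3 lower when adjusted over the list alone.

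Markers of other tissues in the diaphragm pieces varied between libraries. Hepatocyte genes had means from -4.69 in MatKO diaphragm 1 to 1.42 in MatKO diaphragm 3, and Alb ran from 27.6 to 2832 CPM in those libraries. As a list they were lower (16 measured, 0 called, 0 when adjusted over the list alone, median -0.21, adjusted p = 0.049, and adjusted p = 0.90 with an estimated correlation), with Ttr at -0.76 ± 1.35 and Hp at -0.43 ± 1.33. The median of hepatocyte genes was 0.35 without MatKO replicate 1, where camera turned to higher (adjusted p = 0.64), and the call was also lost without WT replicate 2 (0.17), WT replicate 3 (0.47, with a median of 0.44) or MatKO replicate 2 (0.056). Erythroid genes were lower in the same manner (15 measured, 0 called, 0 when adjusted over the list alone, median -0.43, adjusted p = 0.038, and adjusted p = 0.90 with an estimated correlation), with means from -1.73 in MatKO diaphragm 1 to 0.76 in WT diaphragm 3, Sptb at -0.20 ± 0.09 and Tspo2 at -0.89 ± 0.64. Erythroid genes were not called without WT replicate 2 (0.13), WT replicate 3 (0.78) or MatKO replicate 1 (0.72), and with sex as a covariate neither erythroid (0.57) nor hepatocyte genes (0.37) were. Background subtraction ended both calls (0.053 and 0.053), males only did so too (0.57 and 0.058), and DESeq2 size factors ended that of hepatocyte genes (0.055). Endothelial cell markers (0.67), tendon genes (0.66), Schwann cell genes (0.73) and cartilage and bone genes (0.091) were not called, nor were the remaining lists, all at 0.091 or more. The sex-linked genes had a median of -0.48 where camera pointed higher, mesothelial genes a median of 0.01 where it pointed lower, and Schwann cell genes a median of 0.06 and a mean a little below 0. Single called members of uncalled lists were Plin4 (-0.48 ± 0.09), Abcc9 (-0.31 ± 0.08), Muc16 (-0.38 ± 0.09), H19 (-0.29 ± 0.05), Peg10 (0.34 ± 0.08), Ldha (-0.48 ± 0.08) and, on the X, Kdm5c (0.68 ± 0.14) and Ddx3x (0.40 ± 0.10).

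In all, 429 of 15416 genes were called in diaphragm, 149 higher and 280 lower, and 79 changed at least 2-fold (27 higher, 52 lower). Groups did not overlap for any of the 429, against 18.4% of all genes tested and 10% by chance. The largest increases, beside Rtl1 and Mir3071, included Nmrk2, an NAD synthesis kinase (3.06 ± 0.52), Hoxc10 (1.86 ± 0.47), Sbk2 (1.79 ± 0.31), Stmnd1 (1.69 ± 0.29), Paqr8 (1.56 ± 0.24) and the small heat shock protein Hspb6 (1.48 ± 0.09), which went from 132 ± 13.0 to 370 ± 42.5 CPM. The largest decreases included glucokinase, Gck (-3.75 ± 0.55), the tubulin Tuba8 (-2.79 ± 0.28), Aldh1a7 (-2.32 ± 0.43), Tmem72 (-2.20 ± 0.29), Il17re (-1.96 ± 0.40) and Klhl33 (-1.71 ± 0.35). With sex as a covariate 69 genes were called, 65 of them among the 429, in males alone, again 1 MatKO against 3 WT with a spread from WT only, 214, with 161 shared, and in a joint fit of 12 libraries 161, with 145 shared. All 429 kept their direction with sex and in males alone, with median ratios of log2 fold changes of 0.993 and 0.989. Both fits rest on the 1 male MatKO diaphragm, which already lay on the called side of every WT since no groups overlapped. The kept direction was thus fixed in advance and says nothing about sex. Leaving out WT replicate 1, 2 or 3 gave 180, 212 and 237 genes, and leaving out MatKO replicate 1 or 2 gave 214 and 230. Without MatKO replicate 3, labelled abnormal, the count rose to 532, with 43.4% higher against 34.7% of the 429. Of the 62 called genes that the naming rule picked beside Rtl1, 31 passed whichever library was left out and 19 with sex as a covariate. The 18 that passed in all of these and with background reads taken off are Pvalb, Actn3, Myh4, Mylk2, Mir434, Mir3071, Fbxo32, Hdac4, Chrng, Scn4a, Musk, Hspb6, Pdk4, Trdn, Ccng1, Tuba8, Paqr8 and Nmrk2. Mir432, Runx1, Mstn, Hrc, Sypl2 and Gck passed whichever library was left out but not with sex as a covariate. With single libraries left out the number was 36, 39 and 36 without WT replicate 1, 2 or 3, and 39, 44 and 50 without MatKO replicate 1, 2 or 3.

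Genotype effects on single genes differed between the tissues. Fbxo32 (1.76 ± 0.16, diaphragm minus placenta, adjusted p = 2.5e-05), Pdk4 (1.67 ± 0.16), Mrpl34, a mitochondrial ribosomal protein gene (1.49 ± 0.20), Runx1 (1.16 ± 0.17) and Tppp3 (1.71 ± 0.25) had the more positive effect in diaphragm. Camk2a (-3.25 ± 0.34), Vwa1, a matrix gene (-2.30 ± 0.27), Mdga1 (-3.35 ± 0.40), Cd93, an endothelial receptor (-1.09 ± 0.13), and Klhl31 (-3.26 ± 0.42) had the more positive effect in placenta. Mdga1 and Klhl31 have few counts in placenta and Camk2a has 2 to 5 in each WT placenta, so their fitted sizes depend on the prior count. Of 18612 genes, 161 passed, 58 with the more positive effect in diaphragm and 103 in placenta. With sex as a covariate 11 passed, in males only 26, with the DESeq2 Wald test 364 and with no filter 456. Without MatKO replicate 2 in both tissues 899 did, where all MatKO libraries left are female and all WT libraries male. Taking placenta and diaphragm of a genotype and number as 1 animal gave 79, with 29 more positive in diaphragm and 50 in placenta. Leaving out WT replicate 1, 2 or 3 gave 37, 67 and 48, and leaving out MatKO replicate 1 or 3 gave 50 and 82.

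Across the 13728 genes tested in both tissues, the log2 fold changes had a Pearson correlation of -0.02 and a Spearman correlation of -0.03; genes are not independent replicates, and no p was computed. The Pearson value was 0.03 without WT replicate 2 and 0.08 without MatKO replicate 2. Genes called in both tissues were few. Rtl1 and Mir3071 rose in both, against 1.31 expected by chance for independent genes. Mir3071 lies inside Rtl1 on the same strand and may count the same RNA, so the 2 are not separate cases. The fatty acid desaturase gene Scd2 fell in both (-0.52 ± 0.10 in placenta, -0.64 ± 0.09 in diaphragm), against 0.283 expected. Camk2a (3.01 and -0.32) and B230312C02Rik (1.07 and -3.56) rose in placenta and fell in diaphragm, against 1.85 expected. Scd2 and B230312C02Rik were named after their values were seen, since they complete these counts.

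**Figure D5:**
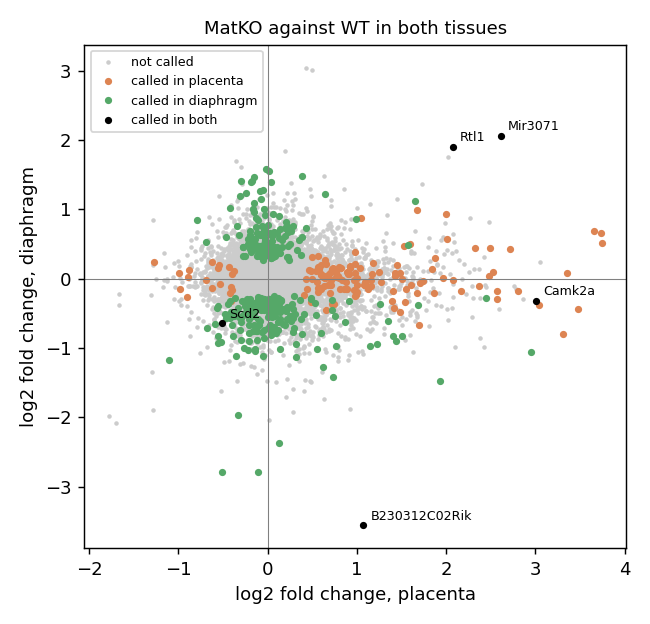
Log2 fold change of MatKO against WT in placenta (x axis) and in diaphragm (y axis), with 1 point for each of the 13728 genes tested in both and colours for where a gene was called. Rtl1 and Mir3071 lie high on both axes, and the cloud shows no slope (r = -0.02).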

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

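A tested difference between tissues flagged 161 genes, and the 35 below are those that the naming rule also reached. Values are log2 fold changes of MatKO against WT in diaphragm minus those in placenta, and the regroupings, background subtraction and males only were chosen only after the result was seen. More positive in diaphragm were Fbxo32 (1.76), Tppp3 (1.71), Pdk4 (1.67), Atf3 (1.65), Paqr8 (1.60), Fos (1.55), Prx (1.55), Mrpl34 (1.49), Hspb6 (1.16), Runx1 (1.16), Ltbp2 (1.13), Hdac4 (0.92) and Egln3 (0.91). For Prx, Ltbp2 and Egln3 the change itself lies in placenta, where they fell.

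More positive in placenta were Aldh1a7 (-8.00), Pvalb (-5.86), Gck (-5.19), Mir434 (-4.81), Fam81a (-4.04), Mdga1 (-3.35), Klhl31 (-3.26), Camk2a (-3.25), Myh4 (-2.91), Nek10 (-2.90), Trdn (-2.78), Aplnr (-2.70), Vwa1 (-2.30), Tuba8 (-2.22), Actn3 (-2.13), Apln (-1.81), Bmp2 (-1.78), Emcn (-1.65), Cldn5 (-1.18), Cd93 (-1.09), Abcc9 (-0.98) and Ccng1 (-0.65). Many of these were reached as called members of vessel or muscle lists, so no theme can be read from them. For Pvalb, Klhl31, Myh4, Trdn, Actn3, Aldh1a7, Gck, Mdga1 and Mir434 the placental counts are few, and for Camk2a, Fam81a and Nek10 those of the WT placentas are, so the fitted sizes depend on the prior count. Mir434 also had only 2, 0 and 1 counts in the MatKO diaphragms. Pvalb, Gck, Mir434, Myh4, Trdn and Aldh1a7 were called lower in diaphragm and had too few counts for a test in placenta alone. For these genes no rise in placenta is thus shown. For Ccng1 (0.00 in placenta, -0.70 in diaphragm) and Tuba8 (-0.51 and -2.79) the larger change is a fall in diaphragm.

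Over 100 regroupings of the libraries, a number raised after a first smaller count was seen, 2 gave at least 161 genes with a difference between tissues, the real one among them. The other had 172 genes and kept the real split of the diaphragms, while it set WT placenta 2 beside MatKO placentas 1 and 3, and a further one had 131. So few groupings reach this count, but 1 that mixes genotypes in placenta does. With background reads taken off, 144 of the 161 genes were called again, and the 10 genes named for the tissue difference in the comparison above kept their calls. Those 10 also kept them whichever replicate was left out, while 7 did in males only (1 MatKO against 3 WT in each tissue) and 5 with sex as a covariate.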

How the results depend on the processing

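Changes of setting moved counts more than directions. For called genes, though, the directions with sex, in males only and with a replicate left out were fixed by groups that did not overlap. Males only for lists, for the tissue difference and for the correlation, background subtraction, and the correlation without replicates 1 and 2 were chosen after seeing the data. Without MatKO replicate 2, all MatKO libraries left are female, so genotype cannot be told apart from sex in those fits. Genes changed in placenta (183) were 296 with the DESeq2 Wald test, 103 with limma-voom, 574 with no filter, 55 with sex as a covariate, 87 in males only and 53 to 2012 with a replicate left out. Gene lists in placenta (10) were 0 with an estimated correlation, 2 with fry, 20 with no filter and 5 to 12 with a replicate left out. The 10 were 3 higher and 7 lower, while the 20 with no filter were 0 higher and 20 lower. Genes changed in diaphragm (429) were 69 with sex, 214 in males only, 161 in the joint fit and 180 to 532 with a replicate left out, and the share higher, 34.7%, was 50.7% with sex. Gene lists in diaphragm (11) were 0 with an estimated correlation, 1 with fry, 18 with fry for mixed directions and 8 to 15 with a replicate left out. Of the 10 and 11 lists called, 8 and 9 passed again with background subtracted, 6 and 8 at 2 times the rate, 4 and 7 in males only, and 10 and 10 with DESeq2 size factors. Genes that differ between tissues (161) were 364 with DESeq2, 456 with no filter, 11 with sex, 26 in males only and 37 to 899 with a replicate left out. The correlation (-0.02) was 0.0796 in males only and -0.0735 to 0.0807 with a replicate left out. Rtl1 kept its value throughout (1.99 to 2.15 in placenta, 1.85 to 2.02 in diaphragm). Directions turned for Xist in placenta (-0.63 with sex, -0.63 in males only), replication-dependent histone genes (median 0.0279 with sex), trophoblast giant cell markers (by camera, medians -0.0260 with sex and -0.0244 in males only), mural cell markers and angiogenic signalling genes with no filter (by camera, medians 0.10 and 0.14) and hepatocyte genes without MatKO replicate 1 (0.35; their range was -2.06 to 0.44 with a replicate left out). The replicate number as a block gave 129 and 493 genes in placenta and diaphragm. With it 7 lists were called in placenta (1 higher, 6 lower) and 12 in diaphragm (5 higher, 7 lower). For the tissue difference the block took placenta and diaphragm of a genotype and number as 1 animal, and gave 79 genes. Whether numbers pair samples stays undecided. Deviations of WT and MatKO with the same number correlated at -0.22 to -0.06 in placenta, where other pairs had -0.05 to 0.17, but at 0.02 to 0.46 in diaphragm, where other pairs had -0.44 to 0.11. Placenta and diaphragm with the same number correlated at 0.102, 0.0981 and 0.0635 in WT, where other pairs had -0.0926 to 0.00300, and at -0.0531, 0.106 and 0.101 in MatKO, where other pairs had -0.164 to 0.105. The cause of these shifts was not tested.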

Other observations

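Single genes outside the fixed lists that are known from endothelium were also called in MatKO placenta. They were chosen after their values were seen, so they stand for no group, and no theme was tested. Lyve1, the hyaluronan receptor of lymphatic and some fetal endothelium, rose by 1.75 ± 0.13, Cd93 by 1.09 ± 0.09, Cd34 by 1.08 ± 0.13, the sphingosine phosphate receptor S1pr1 by 0.80 ± 0.10 and the scavenger receptor Stab1 by 0.65 ± 0.12. The transcription factor genes Fli1, Sox7, Mef2c and Ets1 were higher as well, with Fli1 at 1.16 ± 0.19, Sox7 at 1.00 ± 0.14, Mef2c at 0.99 ± 0.19 and Ets1 at 0.93 ± 0.09. Other genes known from endothelium did not pass the threshold, with Kdr at 0.10 ± 0.08, Pecam1 at 0.24 ± 0.09 and Vwf at -0.29 ± 0.12, which leaves smaller changes open.

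In MatKO diaphragm, some single enzyme and transporter genes of sugar and energy use were called lower, again chosen after their values were seen and with no theme tested. Gpd1 fell by 1.21 ± 0.09, Ampd1 by 1.14 ± 0.08, Phkg1 by 0.71 ± 0.14, Gbe1 by 0.62 ± 0.12, Eno3 by 0.58 ± 0.07, Slc2a4 by 0.50 ± 0.08, Agl by 0.48 ± 0.07, Pfkm by 0.44 ± 0.07 and Pygm by 0.39 ± 0.07. Srebf1, the regulator of fat synthesis, fell by 0.75 ± 0.10 and Thrsp by 1.18 ± 0.11. Of genes for chaperones and their partners, chosen in the same manner, 5 that were higher are Dnaja4 at 0.72 ± 0.09, Hsp90aa1 at 0.69 ± 0.12, Stip1 at 0.62 ± 0.08, Bag2 at 0.60 ± 0.11 and Hsp90ab1 at 0.45 ± 0.07.

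These fuel genes led to a guess, made after Pdk4, Srebf1 and Thrsp were seen, that MatKO diaphragm may have a fasting-like state; its test on lipogenic genes was chosen only after the result was seen, and that on fasting-induced genes was fixed ahead of their values. Lipogenic genes without Thrsp were lower as a list (10 measured, 0 called, 3 lower when adjusted over the list alone, median -0.37, camera p = 0.0042 and adjusted p = 0.0084 over both lists), which goes with the guess, although p was 0.31 with an estimated correlation. Including Thrsp, these were 3.3e-04 and 0.17. Many of these genes are also expressed in liver, and hepatocyte means in the diaphragm pieces ran from -4.69 to 1.42, with Scd1 at -1.24 ± 0.52 and Hmgcs2 at 0.23 ± 1.39, so liver in the pieces stays open as a source. Fasting-induced genes did not pass as a list (10 measured, median 0.13, camera adjusted p = 0.60): Ucp3 rose by 1.15 ± 0.22 and Irs2 by 0.47 ± 0.11 while Ppargc1a fell by 0.57 ± 0.13. The guess stays open, and measured lipids or glycogen could settle it.

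For the rise of endothelial markers in placenta, every test was chosen only after the result was seen. With background reads taken off, the list median was 0.39 beside 0.37, which argues against those reads as its source. Endothelial markers exceeded labyrinth trophoblast markers by 0.41 ± 0.12 on average, an error over genes that leaves out the spread between libraries. The endothelial mean was 0.34, 0.45 and 0.39 in MatKO placentas 1, 2 and 3. Means of the labyrinth trophoblast lists were at most 0.16 in those libraries, which argues against a larger share of labyrinth in the piece sampled. In the 1 male MatKO placenta the median was 0.49, and with a single library an effect of sex cannot be told apart from one of genotype.

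For the fall of fast fibre genes in diaphragm, every test was again chosen only after the result was seen. Fast fibre genes lay under slow fibre and other sarcomere genes by 0.77 on average (-0.77 ± 0.20), again with an error over genes. The fast fibre mean was -0.66, -0.68 and -0.68 in MatKO diaphragms 1, 2 and 3. Means of the slow fibre and other sarcomere lists were no lower than -0.085 there. That argues against a smaller share of muscle in the piece sampled as the source of the whole fall. Medians over the genes of those lists were both -0.07, with 4 of 12 and 10 of 25 genes above 0. A slightly smaller share of muscle thus stays open. Developmental myosin genes had a mean of 0.0510 ± 0.0933 (error over genes), so that fewer mature fibres cannot be told apart from a shift of fibre type. In the 1 male MatKO diaphragm the median was -0.43, and sex stays open for the same reason.

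For the added genes with reads in MatKO placentas 1 and 3, the test of even spread was fixed ahead of its value and the others were chosen only after the result was seen. Genes without a read in the WT placentas held 1.69 times the reads that the olfactory receptor rate predicts, within the bounds set for reads spread evenly over the genome, though MatKO placenta 2 had a like ratio of 1.72 at a lower rate. At 7.48 M counts each, both libraries still had at least 1.34 times the genes of any other placenta, which argues against library size. The highest female diaphragm had 1.05 times the olfactory receptor rate of the highest male, and since both placentas are the only females, sex stays open. Whether DNA in the RNA is the source was not measured.

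Regroupings of the libraries, chosen only after the result was seen, are few at 10 per tissue, too few to judge by. In placenta 183 genes were called in the real grouping and at most 0 in any other (1 of 10 as large), and 10 lists against at most 10 (2 of 10). In diaphragm the numbers were 429 genes against 25 (1 of 10) and 11 lists against 12 (2 of 10). Of 100 joint regroupings, 67 had a correlation across tissues at least as far from 0 as -0.02, with the highest other at 0.20, so other groupings often give a value as large.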
